A study of Mus musculus with 2 samples.

How the data were processed

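Single-cell RNA sequencing was compared between 1 library of wild-type mouse lung and 1 library of lung from a TLR9-based mouse model of macrophage activation syndrome (MAS), both on the C57BL/6 background. MAS is a state of excessive activation of macrophages and lymphocytes with high cytokine levels, and TLR9 is an innate receptor for unmethylated CpG DNA. Per the labels' protocols, 25 mg of fresh lung was dissociated on ice with collagenase, elastase, neutral protease and a Bacillus licheniformis enzyme mix, red cells were lysed, and 15000 cells of each kind were loaded into separate lanes of a 10x Genomics Chromium instrument for 3' v3 libraries. The labels do not say how many mice each library holds, whether the lungs were perfused, or how the MAS model was induced. Group and lane cannot be told apart in this design.

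The submitters' processing notes name Cell Ranger and the build mm10. How cells were filtered, whether doublets were removed, and how cells were clustered, named and embedded are not given in the sources used here. The deposited table of cells gives for each cell a barcode, its library, 1 of 30 cluster names set by the authors, and its 2 UMAP coordinates, a planar embedding in which cells of similar expression are placed near each other and which has no unit. The table holds 14954 cells, 7923 from wild-type lung and 7031 from MAS lung, which are 52.8% and 46.9% of the cells loaded. The barcode list and the feature list were identical in both libraries, with 6794880 barcodes and 28692 genes, and all 14954 annotated barcodes were in the list. No expression values per cell were used, so no gene is reported by value, doublets could not be called, UMI depth per cell is unknown, and the cluster names were taken as the authors gave them. The gene-level part of the planned comparison was therefore not run. 13 barcodes were annotated in both libraries, against 8.20 by chance, and 1 of the 13 carried the same cluster name in both. They were kept, and leaving them out was an alternative.

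Shares of annotated cells were computed in Python 3.11.15 with SciPy 1.17.1 and NumPy 2.4.6, and figures were drawn with Matplotlib 3.10.9. Each share has an exact Clopper-Pearson 95% binomial interval, and each log2 ratio of shares (MAS over wild-type) has a delta-method 95% counting interval. Where a library held 1 to 3 cells of a cluster, the fold has an exact conditional binomial interval in its place. Where a library held 0 cells, the fold is given against a floor of 3 cells in that library, which is not a 95% bound, beside the exact lower limit of the fold. All intervals and floors cover counting error only. With 1 library per group no test between groups was made, no p-value is given, and the spread between animals is unknown. On simulated cells drawn from the wild-type shares, with 200 simulations for each of 5 fold sizes from 0.25 to 4, the interval held the true log2 ratio in 95% to 97.5% of simulations. Each simulation changed 1 of the 24 clusters with at least 20 wild-type cells. Coverage was not simulated for smaller clusters or for folds outside that range, such as those of classical monocytes, inflammatory monocytes and AT1 cells.

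Clusters were put into 8 broad classes by word lists that were fixed before the data were examined. After the table was seen, 3 clusters whose names the lists did not match were assigned by hand. The T lymphocyte clusters 21 and 42 were put with T and NK cells, and the Langerhans cells with dendritic cells. The word lists alone are given as an alternative. The name MyoF-FibM was matched by no word and was left unclassed, and megakaryocytes were kept outside both the immune and the non-immune cells. Also fixed before the data were examined was the rule for the clusters described one by one. These were every macrophage or monocyte cluster and, of all other clusters with at least 30 cells, the 10 with the largest absolute log2 ratio among those whose binomial intervals did not overlap. 14 clusters were eligible. Clusters named outside that rule were chosen after their values were seen. Shares were also computed within macrophages and monocytes, within immune cells, within non-immune cells, and among all cells other than macrophages and monocytes (added for the broad classes after the data were seen), because a share of all cells must go down in some types when it goes up in others. The alternatives changed the denominator, left out the largest cluster of a library, small clusters, megakaryocytes or the barcodes seen in both libraries, used counts per 15000 cells loaded, used Wilson intervals, and used a centred log ratio.

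For the closing section, a separation index was computed from the UMAP coordinates. 40 cells per library were drawn from a cluster, the share of each cell's 10 nearest neighbours that came from its own library was averaged, and the index was the excess over the share given by random mixing, divided by the largest possible excess. An index of 0 means that the libraries were mixed and 1 that they were apart. It was averaged over 100 draws in each of the 15 clusters with at least 40 cells per library. In simulated mixed libraries it was 0.005 and in libraries placed far apart it was 1.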

Results

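Cells of whole dissociated lung were profiled by droplet-based single-cell RNA sequencing in wild-type mice and in a TLR9-based mouse model of macrophage activation syndrome (MAS), with 1 library per group. The series concerns the part played by interferon-gamma and alveolar macrophages in the lung inflammation of MAS, and these libraries address which immune and parenchymal cells make up the inflamed lung. The authors annotated 7923 wild-type and 7031 MAS cells in 30 clusters. The data analysed here are cell identities and not gene expression, so each comparison below is of the number of cells of a type. Intervals are 95% intervals that cover counting error only, and no test between groups was possible with 1 library of each.

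The MAS library was dominated by macrophages and monocytes. These phagocytes made up 57.2% of MAS cells (interval 56.0% to 58.4%, 4021 cells) and 16.7% of wild-type cells (15.9% to 17.6%, 1325 cells), a 3.42-fold higher share with a log2 ratio of 1.77 (1.70 to 1.85). The largest cluster of the class was alveolar macrophages in wild-type lung (59.8% of the class) and classical monocytes in MAS lung (39.3%). The immune cells as a whole numbered 4.94 per non-immune cell in MAS lung and 1.19 in wild-type lung. Of the 18 immune clusters, 8 had a higher share in MAS lung with an interval of the log2 ratio that excluded 0, 3 had a lower share, and 7 had an interval that included 0. All 10 non-immune clusters had a lower share in MAS lung.

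**Figure D1:**
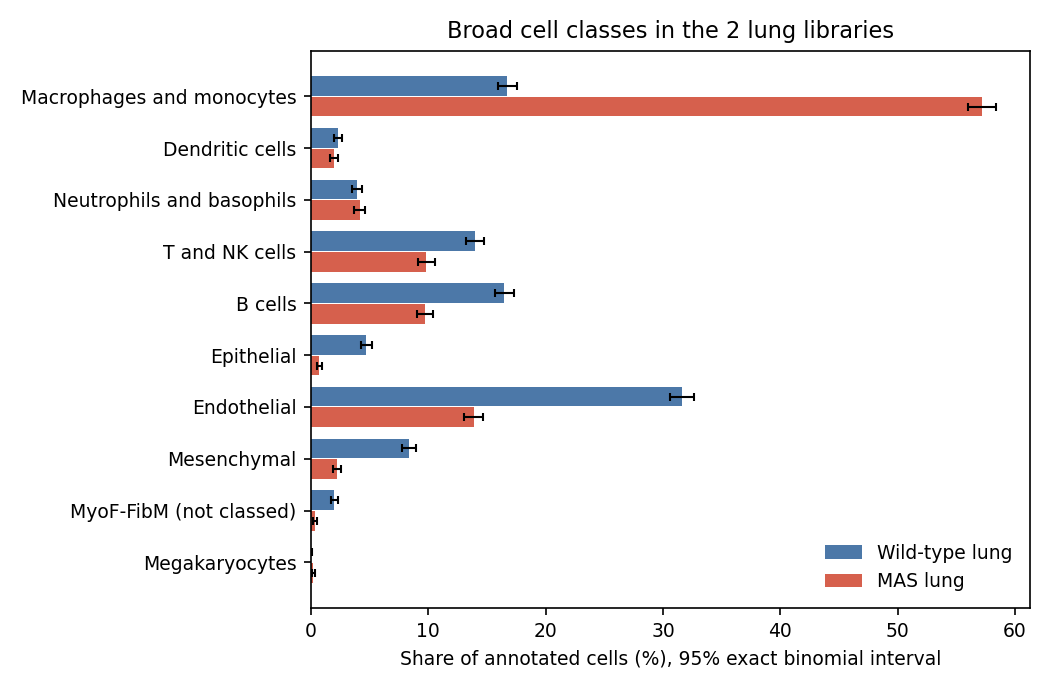
Share of annotated cells (%) in each broad class, with wild-type lung in blue and MAS lung in red, 1 library each; error bars are exact 95% binomial intervals. Macrophages and monocytes went from 16.7% to 57.2% while epithelial, endothelial and mesenchymal shares were all lower in MAS lung.

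Alveolar macrophages, the resident phagocytes of the airspace, took almost the same share of all cells in both libraries. They were 10.0% of wild-type cells (9.34% to 10.7%, 792 cells) and 9.36% of MAS cells (8.69% to 10.1%, 658 cells), with a log2 ratio of -0.10 (-0.24 to 0.05). Monocyte clusters differed far more. Classical monocytes, the blood monocytes that enter inflamed tissue, were 22.5% of MAS cells (1581 cells) and 1.60% of wild-type cells (127 cells), a 14.0-fold higher share with a log2 ratio of 3.81 (3.55 to 4.07). Inflammatory monocytes were 4.07% of MAS cells (286 cells) and 0.0757% of wild-type cells (6 cells), a log2 ratio of 5.75 (4.58 to 6.91). The cluster that the authors named extravasating interstitial mono-mac was 10.8% of MAS and 4.40% of wild-type cells, a 2.45-fold higher share. Mature interstitial macrophages, the phagocytes of the lung's connective tissue, were 0.768% of MAS and 0.631% of wild-type cells, and the interval of their log2 ratio of 0.28 included 0 (-0.27 to 0.84).

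A pair of macrophage clusters came almost only from MAS lung. Cluster 30 held 497 MAS cells (7.07% of the library, 6.48% to 7.69%) and 0 of 7923 wild-type cells. Against the floor of 3 wild-type cells (0.0379%), its share was 187-fold higher in MAS lung. The exact upper limit of its wild-type share was 0.0465%, and the exact lower limit of the fold was 151. Cluster 17 held 185 MAS cells (2.63%) and 1 wild-type cell, a ratio of 208 with an exact interval from 37.0 to 8278. The authors named both clusters MAS-specific macrophages from these same libraries, so their difference is not independent evidence, and with 1 library per group a cluster made up of 1 library can reflect that library. Without both clusters, macrophages and monocytes were still 52.6% of MAS cells and 16.7% of wild-type cells, a log2 ratio of 1.65 (1.58 to 1.73).

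**Figure D2:**
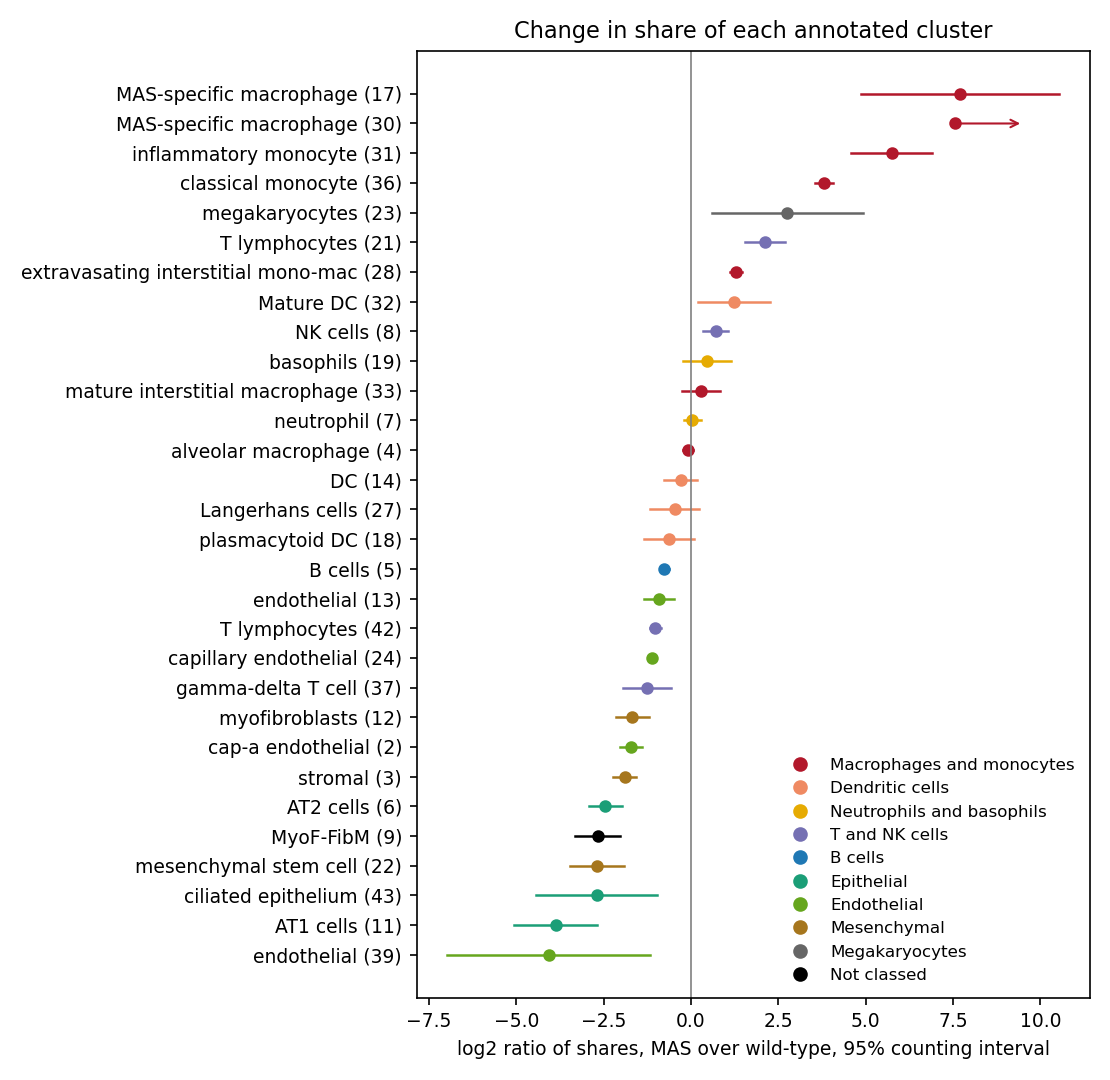
Log2 ratio of the share of annotated cells, MAS over wild-type, for each of the 30 clusters (cluster number in parentheses), coloured by broad class; lines are 95% counting intervals. The arrow marks the floor value for cluster 30, which had 0 wild-type cells and was set against a floor of 3. Monocyte and MAS-specific macrophage clusters lie farthest to the right, and AT1 cells and endothelial cluster 39 farthest to the left, with 6 and 1 MAS cells.

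The make-up of the phagocyte compartment therefore differed between the libraries. Alveolar macrophages were 59.8% of wild-type macrophages and monocytes (57.1% to 62.4%) and 16.4% of those in MAS lung (15.2% to 17.5%), a log2 ratio of -1.87 (-1.99 to -1.75). Classical and inflammatory monocytes together were 10.0% of this compartment in wild-type lung and 46.4% in MAS lung. MAS-specific macrophages were 17.0% of it in MAS lung, 682 of 4021 cells. The mono-mac cluster, although larger among all cells, was a lower part of the compartment in MAS lung, at 18.9% against 26.3% with a log2 ratio of -0.48 (-0.64 to -0.32). Mature interstitial macrophages were 1.34% of it in MAS lung and 3.77% in wild-type lung.

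**Figure D3:**
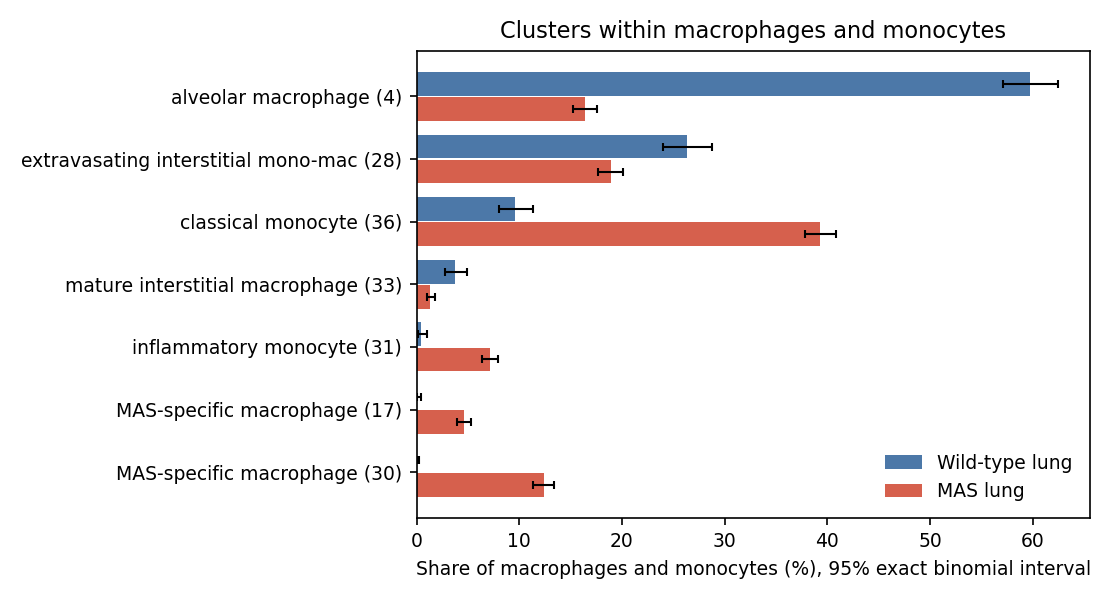
Share of each of 7 clusters among macrophages and monocytes (%), for 1325 wild-type cells (blue) and 4021 MAS cells (red); error bars are exact 95% binomial intervals and cluster numbers are in parentheses. Alveolar macrophages made up 59.8% of the wild-type compartment, and classical monocytes were the largest cluster of the MAS compartment at 39.3%.

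Lymphocytes took a lower share of all cells in the MAS library, with a split among T cell clusters. B cells were 9.70% of MAS cells and 16.5% of wild-type cells, a log2 ratio of -0.76 (-0.89 to -0.64), and the T and NK class was 9.81% against 14.0%, a log2 ratio of -0.51 (-0.64 to -0.38). Within that class, T lymphocyte cluster 21 had a 4.33-fold higher share in MAS lung (119 cells against 31, log2 ratio 2.11, 1.54 to 2.68). Gamma-delta T cells, a T cell lineage with a distinct receptor, had a lower share (23 cells against 62, log2 ratio -1.26, -1.95 to -0.57). The larger T lymphocyte cluster 42 was 5.69% of MAS and 11.5% of wild-type cells, and NK cells were 2.10% and 1.29%, a log2 ratio of 0.71 (0.35 to 1.07). Both were singled out after their values were seen. Cluster 21 was 17.2% of MAS T and NK cells (14.5% to 20.3%) and 2.80% of those in wild-type lung (1.91% to 3.95%). The lower share of the class depends on cluster 42, without which the log2 ratio was 0.74 (0.49 to 1.00), a test added after the data were seen. It also depends on the denominator. Among cells other than macrophages and monocytes, T and NK cells and B cells both had a higher share in MAS lung. The log2 ratios were 0.45 (0.33 to 0.57) and 0.20 (0.08 to 0.32). That denominator was added after the data were seen. Epithelial, endothelial and mesenchymal cells had lower shares of it, so the reversal does not rest on the phagocytes alone.

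Granulocytes and dendritic cells did not differ beyond counting error as shares of all annotated cells. Neutrophils and basophils together were 4.14% of MAS and 3.90% of wild-type cells, with a log2 ratio of 0.09 (-0.14 to 0.31). Dendritic cells were 1.92% and 2.26%, with a log2 ratio of -0.23 (-0.55 to 0.08). The dendritic class held 4 clusters. Mature DC were the only one of them with an interval that excluded 0, at 23 MAS and 11 wild-type cells and a log2 ratio of 1.24 (0.20 to 2.27), and were chosen after their values were seen. On other denominators both classes differed, in a direction set by the denominator. Within immune cells the log2 ratio was -0.55 for granulocytes (-0.77 to -0.32) and -0.87 for dendritic cells (-1.19 to -0.55), and among cells other than macrophages and monocytes it was 1.05 (0.82 to 1.27) and 0.73 (0.41 to 1.04).

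Parenchymal cells were sparse in the MAS library, and epithelial cells were the most reduced of the 3 classes. Epithelial cells were 0.711% of MAS cells (50 cells) and 4.71% of wild-type cells (373 cells), a 6.62-fold lower share with a log2 ratio of -2.73 (-3.15 to -2.30). AT1 cells, the thin cells of the gas exchange surface, numbered 6 in MAS lung and 99 in wild-type lung (log2 ratio -3.87, -5.06 to -2.68). AT2 cells, which make surfactant, numbered 41 and 252 (log2 ratio -2.45, -2.92 to -1.97). Mesenchymal cells were 2.18% of MAS and 8.36% of wild-type cells (log2 ratio -1.94, -2.19 to -1.69). Their clusters had log2 ratios of -2.69 for mesenchymal stem cells (15 MAS and 109 wild-type cells), -1.90 for stromal cells (92 and 387) and -1.68 for myofibroblasts (46 and 166). The unclassed MyoF-FibM cluster numbered 22 and 158 cells (log2 ratio -2.67, -3.31 to -2.03).

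Endothelial cells, which line the vessels, were 13.9% of MAS cells and 31.6% of wild-type cells, a log2 ratio of -1.19 (-1.28 to -1.09). Capillary endothelial cells were 11.5% and 25.0% (log2 ratio -1.12, -1.23 to -1.01), and the cap-a endothelial cluster was 1.41% and 4.63% (log2 ratio -1.72, -2.03 to -1.40). Among non-immune cells alone, endothelial cells were the larger part in MAS lung, at 82.8% against 70.7% (log2 ratio 0.23, 0.18 to 0.27). On that denominator epithelial cells were 4.24% against 10.5% (log2 ratio -1.31, -1.73 to -0.90) and mesenchymal cells 13.0% against 18.7% (log2 ratio -0.53, -0.76 to -0.29). The lower shares of single clusters were smaller there: the log2 ratio was -2.46 for AT1 cells (-3.64 to -1.27), -1.03 for AT2 cells (-1.50 to -0.57), -1.27 for mesenchymal stem cells (-2.05 to -0.50) and -0.49 for stromal cells (-0.80 to -0.17). The intervals of the cap-a cluster (log2 ratio -0.30, -0.61 to 0.002) and of myofibroblasts (-0.26, -0.73 to 0.20) included 0 on that denominator, and capillary endothelial cells were the larger part in MAS lung (0.30, 0.23 to 0.37). Within their own class, AT1 cells had a log2 ratio of -1.15 (-2.26 to -0.04) and mesenchymal stem cells one of -0.75 (-1.48 to -0.01), with share intervals that overlapped between the libraries. Of the 1178 non-immune cells of the MAS library, 50 were epithelial, so statements on epithelial subsets in MAS lung rest on few cells.

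**Figure D4:**
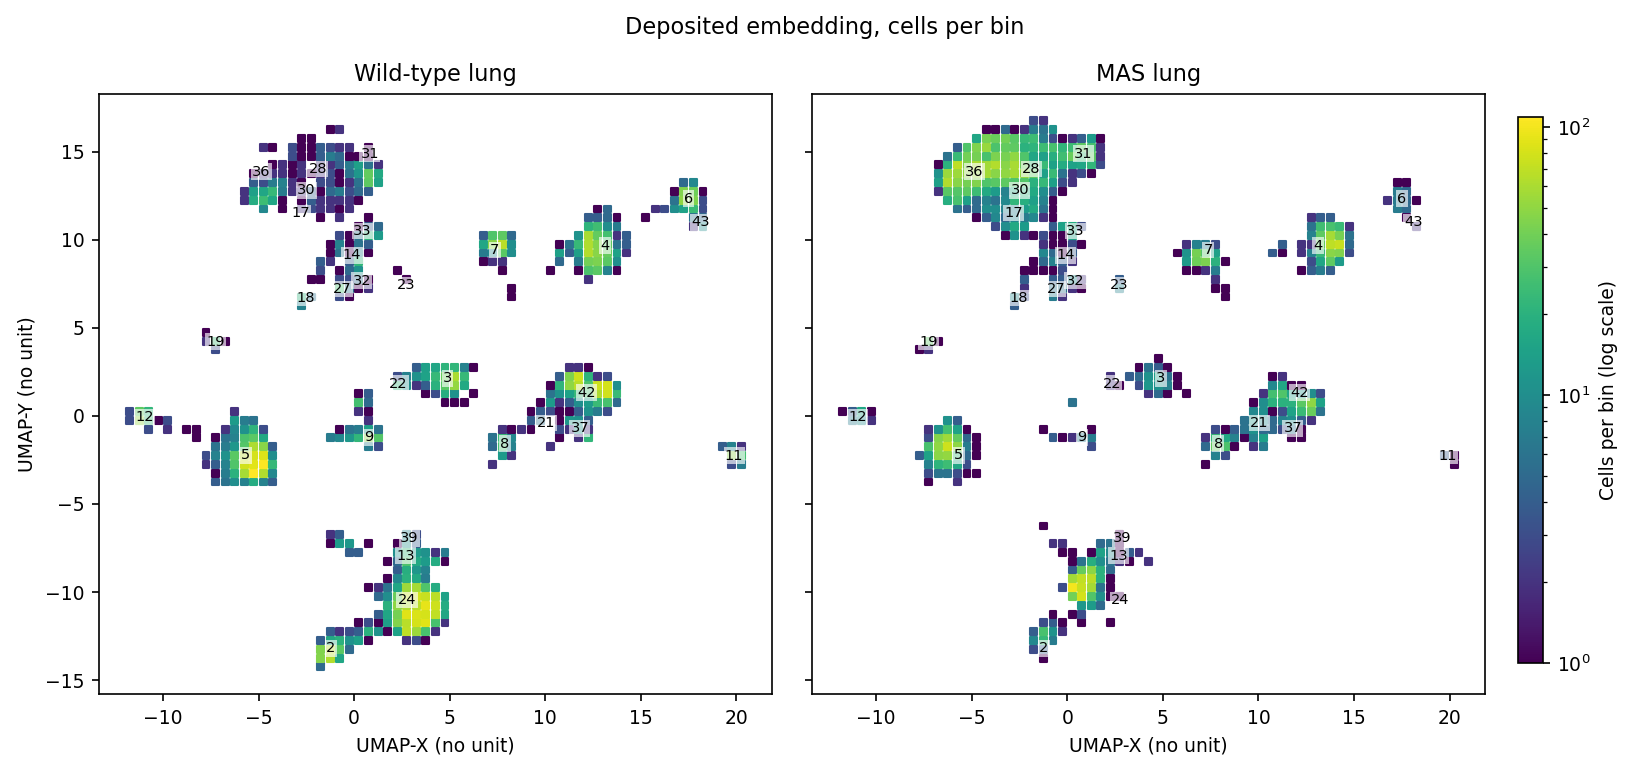
The deposited UMAP embedding (axes without unit) of the wild-type library (left, 7923 cells) and the MAS library (right, 7031 cells); colour gives the number of cells per square bin on a log scale, and numbers mark the median position of each cluster over both libraries (30 is set slightly lower to be legible). The region of clusters 17, 28, 30, 31 and 36 at the top left is filled in MAS lung and sparse in wild-type lung, and AT1 cells (11) number 99 on the left and 6 on the right.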

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

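All values here are log2 ratios, MAS over wild-type. Of the 68 values for the 8 broad classes under alternatives that could change them, 34 stayed within the counting interval of the reported value, 29 moved outside it and 5 reversed, which means a turned sign where the reported interval excluded 0. Dendritic cells and granulocytes, with reported intervals that included 0, also turned sign, to 0.11 and 0.73 and to -0.55, -0.15 and -0.09 (the last per 15000 cells loaded). Wilson intervals cannot move a ratio, and the limits of the shares differed by at most 0.0125 percentage points. The word lists alone, MyoF-FibM counted as mesenchymal, T and NK cells without 1 of the T lymphocyte clusters, and cells other than macrophages and monocytes as the denominator were added after the data were seen. Leaving out the barcodes seen in both libraries, megakaryocytes or clusters under 20 cells, and counting MyoF-FibM as mesenchymal moved no class value outside its interval. Within immune or non-immune cells, macrophages and monocytes gave 1.14, dendritic cells -0.87, granulocytes -0.55, T and NK cells -1.15, B cells -1.40, epithelial cells -1.31, mesenchymal cells -0.53 and endothelial cells 0.23, the last reversed, as were capillary endothelial cells at 0.30; these ratios are relative to compartments whose own shares changed (immune 0.63, non-immune -1.41). Among cells other than macrophages and monocytes, T and NK cells and B cells reversed to 0.45 and 0.197, and dendritic cells, granulocytes, epithelial, endothelial and mesenchymal cells gave 0.73, 1.05, -1.77, -0.23 and -0.98. Without classical monocytes the values were 1.54, 0.11, 0.43, -0.17 and -0.42 for macrophages and monocytes, dendritic cells, granulocytes, T and NK cells and B cells, and -0.84 and -1.60 for endothelial and mesenchymal cells. Without capillary endothelial cells, the largest wild-type cluster, they were 1.54 for macrophages and monocytes, -0.15 for granulocytes, -0.75 for T and NK cells, -1.001 for B cells and -1.73 for endothelial cells. Per 15000 cells loaded they were 1.60, -0.68, -0.94 and -1.36 for macrophages and monocytes, T and NK cells, B cells and endothelial cells, a fixed shift of -0.17. As within immune cells and among cells other than macrophages and monocytes, intervals came to exclude 0 for dendritic cells per 15000 loaded (-0.41, -0.73 to -0.09) and without capillary endothelial cells (-0.47, -0.79 to -0.15), and for granulocytes without classical monocytes (0.43, 0.20 to 0.66). With the word lists alone, T and NK cells reversed to 0.23 (-0.07 to 0.54), because both T lymphocyte clusters left the class; leaving out cluster 42 alone reversed them to 0.74 and cluster 21 alone gave -0.74.

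Within macrophages and monocytes against all cells, alveolar macrophages went from -1.87 to -0.10 (and to -1.73 with dendritic cells in the denominator), classical monocytes from 2.04 to 3.81, inflammatory monocytes from 3.97 to 5.75 and the floor value of cluster 30 from 5.77 to 7.54, while mono-mac cells and mature interstitial macrophages reversed, from -0.48 to 1.295 and from -1.49 to 0.28. The log2 of the immune to non-immune ratio, 2.05, was 1.93 without classical monocytes and B cells and 2.29 with the word lists alone. Set against cells of their own class, AT2 cells, capillary endothelial cells, stromal cells and myofibroblasts turned sign to 0.28 (0.07 to 0.49), 0.071 (0.02 to 0.12), 0.041 (-0.17 to 0.25) and 0.26 (-0.14 to 0.66). The ratio intervals of stromal cells and myofibroblasts included 0. Those of AT2 and capillary endothelial cells excluded 0, while their share intervals overlapped between the libraries, so the criteria disagree for these clusters. Cell number limits AT1 cells, inflammatory monocytes and clusters 17, 23, 30, 39 and 43, each with 6 or fewer cells in a library.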

Other observations

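The tests in this part were chosen after the cell counts were seen. The prediction for the separation of alveolar macrophages between libraries was written before that index was computed.

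Megakaryocytes, the platelet-forming cells, numbered 12 in MAS lung and 2 in wild-type lung, a ratio of 6.76 with an exact interval from 1.51 to 62.2. Ciliated epithelium numbered 3 and 22 cells, a wild-type to MAS ratio of 6.51 (exact interval 1.96 to 34.0). Endothelial cluster 39 numbered 1 and 19 cells, a ratio of 16.9 (exact interval 2.68 to 701). Endothelial cluster 13 had a log2 ratio of -0.91 (-1.33 to -0.49). Basophils (38 MAS and 31 wild-type cells), plasmacytoid DC (24 and 42), Langerhans cells (27 and 42) and the DC cluster (61 and 84) had log2 ratios of 0.47, -0.64, -0.47 and -0.29, with intervals that included 0. All were chosen after their values were seen.

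Macrophages and monocytes took a larger share of the MAS library and most other classes a smaller one. Dilution by these phagocytes alone would leave the other classes in their wild-type proportions, but among the remaining 3010 MAS and 6598 wild-type cells the epithelial log2 ratio was -1.77 (-2.19 to -1.35), while granulocytes (1.05), dendritic cells (0.73), T and NK cells (0.45) and B cells (0.20) had higher shares in MAS lung. Dilution was thus not the whole cause of the lower epithelial share. Lymphocytes had a higher share on this denominator, but epithelial, endothelial and mesenchymal cells had lower shares of it. With the phagocytes left out, neither lymphocyte class thus had a lower share in MAS lung. Those lower non-immune shares also raise the lymphocyte share, so whether dilution alone explains the lower lymphocyte share of all cells is not settled. Per 15000 cells loaded, the log2 ratio was -0.68 for T and NK cells and -0.94 for B cells. These values are the share ratios with a fixed shift of -0.17, so they cannot decide the question. If the neutrophils and classical monocytes of wild-type lung came from blood, more blood of wild-type make-up in the MAS tissue would raise both alike. The neutrophil log2 ratio was instead lower by a difference of -3.77, with intervals that did not overlap. That premise was not tested, and blood whose own make-up had changed in MAS stays open. Epithelial cells had a log2 ratio lower than endothelial cells by a difference of -1.54 (-1.98 to -1.10), which a lower yield of epithelial cells from inflamed tissue at dissociation and a loss in the lung both predict, so these cannot be told apart. Entry of monocytes into the lung in MAS is a candidate explanation of the monocyte excess that 1 library per group cannot test.

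Alveolar macrophages of the 2 libraries were partly separated in the deposited UMAP, although their share of all cells was almost equal. The separation index was 0.52 ± 0.10 (mean ± SD over 100 draws of the same libraries, not replicates), and 0.55, 0.47 and 0.58 with 5 neighbours, with 20 neighbours and with all cells of the smaller library. The separation was not particular to them. Capillary endothelial cells had an index of 0.91, and alveolar macrophages minus this highest endothelial, lymphoid or mesenchymal value gave -0.39. The median of the other 14 clusters was 0.47. For a shift of the whole library, the prediction was a median within 0.10 of the alveolar macrophage index or above it, and this was met. AT2 cells (0.02), NK cells (0.06), myofibroblasts (0.10) and stromal cells (0.11) lay within 2 SD over draws of 0, a criterion that was not part of the prediction. That SD reflects redrawing of the same cells and not the error of the index. In simulated mixed libraries the index was 0.005 with an SD of 0.04. Myofibroblasts and stromal cells exceeded it by more than 2 of these SD. The low values of AT2 and NK cells speak against an equal shift of every cluster, though AT2 cells had only 41 MAS cells. A technical shift between lanes and a response of many cell types to MAS cannot be told apart here, because each group was 1 lane and distances in an embedding are not expression differences.

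The MAS-specific macrophage clusters held almost no wild-type cells. If clustering had split them off from alveolar macrophages, their nearest wild-type phagocyte in the UMAP would be alveolar, but that held for 0.587% of the 682 cells (0.160% to 1.49%), although alveolar macrophages were the most numerous wild-type phagocytes. The nearest wild-type phagocyte was a mono-mac cell for 96.2% of cluster 30 and a classical monocyte for 81.1% of cluster 17. Whether clustering split these cells off from the mono-mac or classical monocyte clusters was not tested. A library shift strong enough to split clusters by library stays open: 0 of the 23 clusters outside the phagocytes (0%) had under 1% of their cells from a library at equal totals, but a named cluster can span libraries that lie apart, as capillary endothelial cells did with an index of 0.91. The nearest cells in an embedding speak only against a split of cells that lie together; whether these macrophages descend from monocytes, or are alveolar macrophages with a strongly changed expression, was not tested, nor were doublets.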
